A study of Homo sapiens with 10 samples.

How the data were processed

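Single-cell RNA libraries of the human line Kuramochi were made by inDrop, which encapsulates cells in droplets with barcoded beads and counts molecular identifiers (UMIs). Per the labels, the line is epithelial and BRCA2-mutant, and 10 populations were profiled with 1 library each: untreated cells (C) and cells exposed to olaparib at 1, 2.5, 5, 10, 20, 40, 80, 160 or 320 µM until confluency (T1 to T320). The populations form 1 serial escalation, so no dose has a replicate and every contrast between populations is also a contrast between libraries. The submitters' processing notes name the builds hg38 and GRCh38 and Seurat 2.3.2. The aligner, the counting tool, the gene annotation and the cell filters are not given in the sources used here.

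The matrix deposited by the authors holds a UMI count for each gene and cell, 12373 genes in 18209 cells, with no normalization. In the metadata table deposited by the authors, UMIs and genes per cell are counts and the mitochondrial share is a fraction. Its file name refers to G1. It lists 8240 of the 18209 cells (45.3%) and gives each a state, C or S1 to S5, and how cells were chosen and states assigned is not given in the sources used here. The 7322 listed cells outside T40 were matched to the matrix by name. The 918 listed T40 cells have other names in the table and were matched by barcode, which gave identical UMI totals. UMI totals were 9343704 in C, 5338688 in T1, 3125808 in T2.5, 1976069 in T5, 4215856 in T10, 4253488 in T20, 5049036 in T40, 7524689 in T80, 7624188 in T160 and 2826113 in T320, from 1845, 2312, 1561, 726, 1986, 1461, 2077, 2262, 2645 and 1334 cells. The median UMIs per cell ran from 1145 in T2.5 to 2975 in T80 (2247 in C). Cells held 692 to 17644 UMIs, at least 496 genes and at most 15.1% mitochondrial UMIs. All cells were kept, no further filter was set and no doublet caller was run, so doublets passing the authors' filters remain in the sums. Each library listed a gene either at 0 or in about 1% of its cells or more, so a value listed at 0 is not a measured absence, and no fold is given against it. Log2 differences and slopes are given for such genes with the value taken as 0, so their size is uncertain.

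Counts were summed over the cells of each population and scaled by the library total to CPM. Differences between 2 populations are differences of log2(CPM + 10). A gene was measured in a comparison when it had at least 100 UMIs over the 10 populations and at least 50 CPM in at least 1 of the populations compared, and it counted as higher or lower when the difference was at least 1 on the log2 scale. With 1 library per population these contrasts carry no test. Exact Poisson 95% intervals of folds and exact binomial intervals of shares cover counting error only. Distances are root mean squares of log2 differences over the measured genes, set beside the same value between 2 random parts, equal in number, of the cells of 1 population. At the depth of these libraries, such parts differed by 0.0949 in C and by 0.215 in T5, the shallowest library.

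The trend along the escalation was tested on the summed counts of the 11387 genes with at least 100 UMIs, with edgeR's quasi-likelihood F-test of a slope per step (0 to 9, by rank of dose; TMM scaling; 8 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all tested genes and, for gene lists, also over the list alone, with 0.05 as the threshold. The test treats the populations as independent, which 1 serial escalation does not give. On simulated data it recovered 1 of 100 genes with a 2-fold total change and 33 of 100 with a 4-fold change, with 5 false calls. A first simulation with 1 common dispersion gave inflated calls, and the simulation was changed to gene-wise dispersions after that was seen.

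The 40 pathway lists and 5 marker lists had fixed members. For each list with at least 3 measured members, the median log2 difference from C was placed among 10000 random lists of equal size matched on mean expression. That percentile describes these libraries and is not a p-value. Cell-cycle transcripts were summed over a G1/S and a G2/M list, and in a second form counted per cell as the percent of cells with at least 3 UMIs of the list after each cell was thinned to 1000 UMIs, leaving out shallower cells. Genes were named by fixed rules: the 12 highest and 12 lowest differences from C to T320 that were at least 2-fold in the same direction at T160, the 8 steepest slopes in each direction, the 4 most changed in each direction at first exposure and at each of the 3 longest steps, 6 genes highest and 4 lowest in between, the 4 most changed members of each list, and genes fixed for their known roles whatever their values. Symbols made only of a clone name were not named. The text mentions part of the list members that these rules select, and some are not reported here.

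Gene positions and transcript ends came from GENCODE 29 on GRCh38. For 12201 genes the share of 31-mers in the last 500 bases of the transcript that occur in other genes was computed. For 172 genes it could not be. The 2030 genes above 10% are called genes that share sequence. The rules for sizes, trend, lists, naming and most alternatives were set before the data were examined. Chosen after the data were examined were the shared-sequence measure, the settings that leave those genes out before scaling, the endpoint T80 and the trend over C to T80, the naming rule over the remaining genes, the handling of values listed at 0, the scan along the chromosomes, the median of the genes beyond the last window of chromosome 1, and the tally of clustered protocadherins. The scan took windows of 50 neighbouring genes, at 1 window size only, with the genes that share sequence left out, and shuffled the positions 999 times. Set aside after that scan were 3 tests on the 15 genes listed at 0 in C and at 50 CPM or more in T320, and their values are given in the closing part.

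Alternatives covered the scaling (TMM, DESeq2 size factors, ribosomal and mitochondrial genes left out), the pseudocount (1 CPM), the minimum level (none, 200 CPM), equal weight per cell, listed cells only, cells with at least 1145 UMIs, thinning to the shallowest library, the trend tool (DESeq2 Wald test, limma-voom), the covariate (log2 dose, dose), the count filter, and leaving out each population in turn. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The lists of bead barcodes hold no measurement and were not used.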

Results

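Kuramochi is a human ovarian cancer line with a mutation in BRCA2, a gene needed to repair double-strand breaks by homologous recombination. Olaparib blocks PARP enzymes, and cells without homologous recombination are usually sensitive to it. The libraries ask how expression differed as the line went through 1 escalation from untreated (C) to 320 µM olaparib (T320). The 10 populations gave 51277639 UMIs from 18209 cells, 1 library each. Each contrast between 2 populations therefore also holds any difference between 2 libraries. Values are CPM, and differences are log2 values with 10 CPM added to both sides.

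The first comparison asked which genes were higher after the whole escalation. Several code for surface and matrix proteins. CD70, a TNF-family ligand that is mostly confined to activated lymphocytes in healthy tissue, was listed at 0 from C to T5 and reached 172 CPM in T320 (difference 4.19). CD44, a receptor for hyaluronan often used as a marker of stem-like carcinoma cells, was 24.3 CPM in C and 403 in T320 (16.6-fold, counting interval 14.4 to 19.2). LAMA4, a laminin chain of basement membranes, went from 2.68 to 155 CPM (58.1-fold, 38.8 to 90.7). VCAN, a matrix proteoglycan, was listed at 0 in C and at 84.6 CPM in T320, and TGFBI, a matrix protein induced by TGF-beta, at 0 and 99.8. ENG, a co-receptor for TGF-beta, was 26.8-fold higher (20.0 to 36.8; 5.35 and 144 CPM), and TPBG, a surface glycoprotein of trophoblast and carcinoma, 48.2-fold (31 to 79; 2.25 and 108 CPM). DDIT4, an inhibitor of mTORC1 induced by hypoxia and stress, was 15.9-fold higher (13.4 to 19.0; 17.2 and 275 CPM). The phosphodiesterase PDE1C, the protein kinase C isoform PRKCB, the stress kinase TAOK3, the transcription regulator SAMD11 and ZC2HC1A, a zinc finger protein of poorly known function, were listed at 0 in C and at 123, 116, 86.3, 90.6 and 78.6 CPM in T320. CD70 lies on chromosome 19 (6583183 to 6604103, GRCh38), CD44 on chromosome 11 (35138870 to 35232402) and LAMA4 on chromosome 6 (112108760 to 112254939). Intervals cover counting error only, and a gene listed at 0 may have had a UMI in under about 1% of cells.

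Genes lower at T320 included a marker of serous ovarian carcinoma and secreted proteins. WT1, a transcription factor that marks serous ovarian carcinoma, went from 135 CPM in C through 28.9 in T10 to 0 in T160 and T320. Its difference was -3.86, or -4.52 when rescaled with genes that share sequence left out. SPP1, the secreted phosphoprotein osteopontin, was 23-fold lower (18.6 to 28.9; 693 and 30.1 CPM). SPON1, a matrix protein often raised in ovarian tumours, was 35.8-fold lower (24.7 to 53.9; 354 and 9.91 CPM). Listed at 0 in T320 were the protease inhibitor SERPINA5 (138 CPM in C), the synuclein SNCG (137), the tight-junction protein CLDN16 (221), the membrane protein TMEM100 (143), the interferon-induced IFI27 (125), the heparan sulfatase SULF1 (150, with 428 in T10), and FLG (164), which codes for the epidermal protein filaggrin. NMNAT2, an enzyme that makes NAD, the substrate of PARP enzymes, went from 240 CPM in C to 13.8 in T80 and 0 in T320. NMNAT2 (183248237 to 183418602) and FLG (152302175 to 152325203) lie on chromosome 1, whose genes were lower as a group. WT1 lies on chromosome 11 (32387775 to 32435630).

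**Figure D1:**
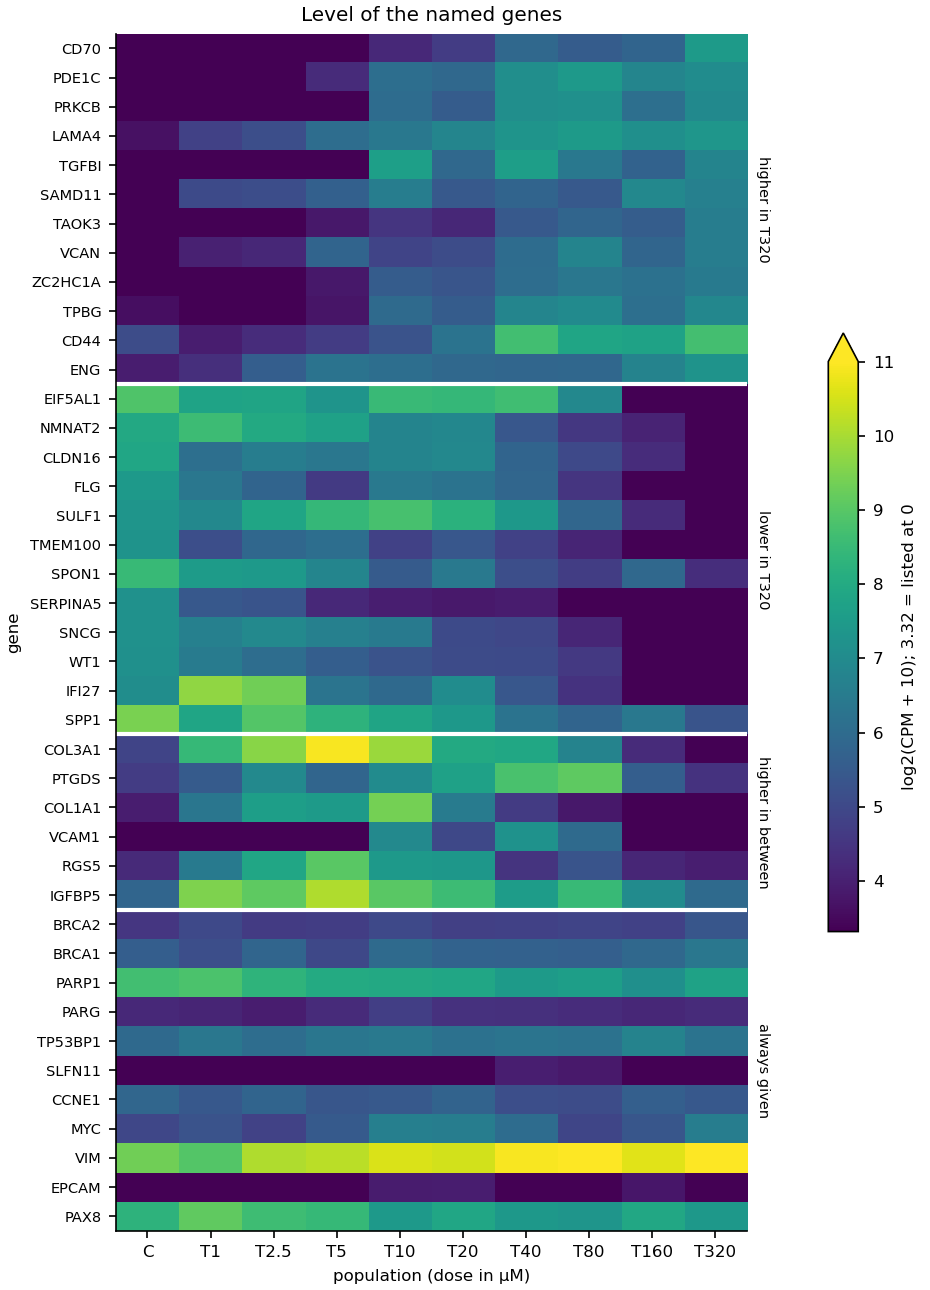
Level of the named genes in each population, as log2 of CPM plus 10, grouped by the rule that selected them. Each population is 1 library.

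How many genes differed depended on the scaling and on the endpoint. From C to T320, 712 genes were higher and 537 lower at least 2-fold among 4617 measured genes, and the median gene stood at 0.12. TMM scaling moved that median to -0.22 and the split to 416 higher and 846 lower, and DESeq2 size factors moved it to -0.16 and gave 450 and 790. Which direction held more genes is therefore open. With genes that share sequence left out the counts were 773 and 585 of 5141 (median 0.08). From C to T80 they were 389 and 547 of 4206, or 520 and 546 of 4907 with those genes left out.

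The genes furthest below C in T320 were mostly housekeeping genes with near copies elsewhere in the genome, and their counts are not read as expression here. The histone gene H3F3A stood at 993 CPM in C and 561 in T80 and at 0 in T160 and T320. The ribosomal protein genes RPS27 (2608 in C, 3214 in T80, 16.9 in T160), RPL7 (3525, 3910 and 45.4) and RPL6 (1025, 1168 and 19.7), the translation factor genes EIF3C and EIF3CL (334 and 330 in C, 0 in T320), the glycolytic gene PGAM1 (303 and 0), the peptidyl-prolyl isomerase gene PPIA (1019 and 41.4) and the mitochondrial rRNA copies MTRNR2L8 (1137 and 35.7) and MTRNR2L12 dropped in the same manner. EIF5AL1 (464 in C, 110 in T80, 0 in T160) resembles EIF5A, and its level is uncertain for this reason, although none of its last 500 bases counted as shared. From T80 to T160 the median difference was 0.27 for 2323 genes with no shared 31-mers and -1.53 for 27 genes sharing over 80%, and from T160 to T320 it was 0.00 for the latter. Ribosomal protein genes were no exception: 16 that share at most 10% had a median of 0.22, and 22 that share over 50% had -1.65. Abrupt drops were counted for genes above 60 CPM in each population from C to T80. In T160 and T320 they had to lie over 4-fold below their lowest level there. Of 39 such genes, 32 share over 10%, and no gene rose abruptly by the mirrored rule. Medians of gene lists below are over all genes, and the value with sharing genes left out is given beside those in T320. Leaving these genes out before scaling also raises the CPM of the rest. More members can then reach 50 CPM, so a list's median can move even where no member shares sequence.

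**Figure D2:**
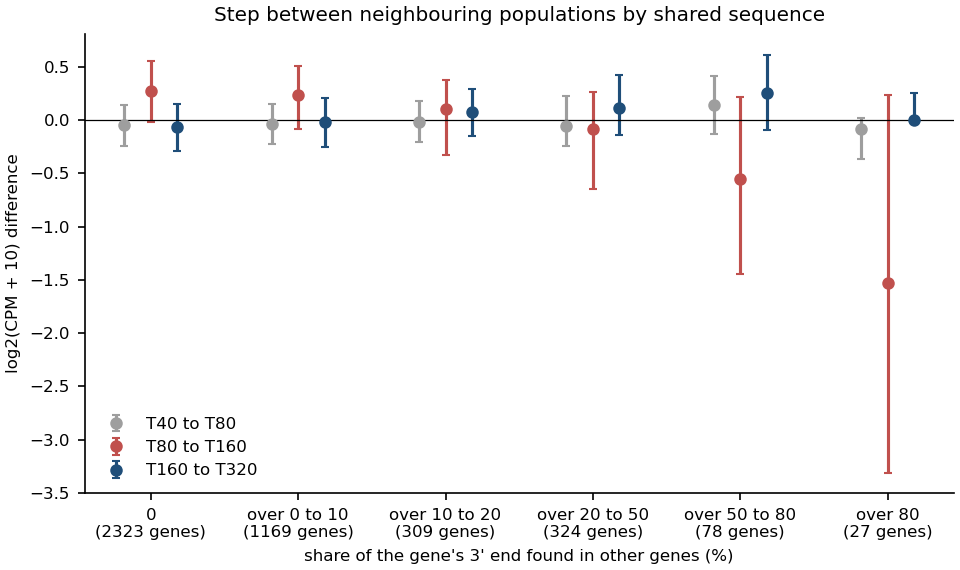
Median and quartiles of the log2 difference at 3 steps, for genes grouped by the percent of 31-mers at the transcript's end that other genes contain. The loss with sharing appears at T80 to T160 alone among the 3 steps.

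The next comparison asked which genes had a slope along the steps of the escalation. Among those that rose, BCHE (butyrylcholinesterase) was listed at 0 until T20, at 14.7 CPM in T40 and at 60.9 in T320, with the steepest slope among genes that reached 50 CPM (1.47 log2 per step by edgeR, adjusted p = 0.00241). Where a gene is listed at 0 in several populations, as BCHE, OSBPL6, CD70 and ARMCX2 are, the fit takes these values as 0. The size, rank and adjusted p of such slopes therefore rest on values that are not measured absences. OSBPL6, a sterol-binding protein, rose from 0 to 63.0 CPM (adjusted p = 0.00241), and SPOCK1, a secreted proteoglycan, from 0 to 98.9 in T80 and 41 in T320 (adjusted p = 0.0113). CD70 (1.12 per step, adjusted p = 0.00139), TAOK3 (0.00228), PDE1C (0.0136), LAMA4 (0.00817), CD44 (0.00903) and DDIT4 (0.00142) rose as well. Steepest among the falling genes by the same minimum was ARMCX2, an armadillo-repeat gene of the X chromosome (82.3 CPM in C, 0 from T10 on; -1.54 per step, adjusted p = 0.00165). APOA1, the main protein of HDL, fell from 29.9 CPM in C and 69.1 in T2.5 to 0 (-1.29, 0.00531), and KLK5, a secreted serine protease raised in ovarian carcinoma, from 38.3 in C and 112 in T2.5 to 0 (-1.02, 0.00755). The anion exchanger SLC26A7 (-1.12, 0.00979), the matrix protein HMCN1 (-1.11, 0.00616; chromosome 1), the differentiation-linked DAPL1 (-1.30, 0.00206; 40.3% shared), SERPINA5 (-1.02, 0.00124), SPP1 (0.00124), SPON1 (0.00239), NMNAT2 (0.00285), SNCG (0.00817) and WT1 (0.0111) fell too.

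By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 914 genes rose and 1024 fell of 11387 (3703 at an unadjusted p under 0.05). The 10 populations come from 1 serial escalation and are not independent, so these p-values describe the order of 1 lineage. Without T320 the counts were 488 and 537, without T80 595 rose, and without T2.5 654 fell. Over C to T80 alone 410 rose and 517 fell, or 365 and 455 with sharing genes left out. Library-size scaling gave 1255 and 755, DESeq2's Wald test 1501 and 1694, and limma-voom 1087 and 1187. The slope of SPOCK1, 1.05 by edgeR, was -0.07 by limma-voom (adjusted p = 0.876). PCDHB10, a clustered protocadherin listed at 0 to T5, at 71.0 CPM in T80 and at 18 in T320, had 0.98 by edgeR (adjusted p = 0.0249) and -0.26 by limma-voom (0.529). Its adjusted p was 0.071 without C, 0.0672 without T1, 0.0605 without T2.5 and 0.0642 without T80. For PRKCB it was 0.0205, but 0.0548 without C, 0.0551 without T1 and 0.0503 without T2.5. Other genes picked by the naming rules also depended on single libraries. Of all those with a trend, 26 lost it at the threshold without T320 and 71 kept it. Without C these numbers were 25 and 72, and over C to T80 they were 38 and 59.

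At first exposure, the question was what 1 µM olaparib went with. The 4 genes furthest above C in T1 code for secreted or surface proteins. PLXNA4, a semaphorin co-receptor, was 30.0-fold higher than in C (24.5 to 37.1; 10.8 and 324 CPM), and IGFBP5, a secreted binder of insulin-like growth factors, 15.5-fold (14.1 to 17.2; 46.6 and 723 CPM). The fibrillar collagen COL3A1 was 17.3-fold higher (14.9 to 20.2; 20.0 and 346 CPM) and the surface proteoglycan GPC3 29.1-fold (21.7 to 39.7; 5.14 and 149 CPM). Lower in T1 were F3, the tissue factor that starts coagulation (10.8-fold, 7.79 to 15.5; 75.1 and 6.93 CPM), UPK1B, a uroplakin of urothelium and other epithelia (9.71-fold, 7.11 to 13.6), STXBP6, a regulator of vesicle fusion (7.74-fold, 6.26 to 9.68), and PIMREG, a mitotic protein (6.49-fold, 5.31 to 8.0). In all, 317 genes were higher and 202 lower of 4186 (median gene -0.07), or 383 and 237 with sharing genes left out. Mitochondrial UMIs made up 11.5% of the C library and 7.15% of T1. The treated libraries ran from 7.08% in T320 to 9.31% in T160, so C was also the highest in a sign of cell quality.

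Interferon-stimulated genes were the list furthest above C in T1, with a median difference of 1.59, above all 10000 matched random lists. Fibroblast markers followed with 1.55 over 4 measured genes, and immediate early and AP-1 genes with 1.36. IFI6, an inhibitor of apoptosis induced by type I interferon, went from 123 CPM in C to 1096 in T1 and 1668 in T2.5. BST2, which tethers budding virus particles, stood at 272 and 826, and IFI27 at 125 and 840. The interferon median stood at 1.18 in T2.5, -0.08 in T10 and 1.19 in T20, and at -0.86 or lower from T40 on. In T320 the list's median was -1.31 (percentile 0.02; -1.74 with sharing genes left out), with 0 of 10 measured members higher and 6 lower, BST2 at 30.1 CPM and IFI6 at 21.2. BST2 (adjusted p = 0.00866), IFI27 (0.00987) and the scramblase PLSCR1 (0.00566; 96.4 to 21.2 CPM) fell by edgeR's trend test. Of 30 members tested, 0 rose and 9 fell (11 adjusted over the list alone), and over C to T80 2 fell. MHC class I genes were higher in T2.5 (median 1.04, above all matched lists) and stood at percentile 40.5 in T320 (4.79 with sharing genes left out). The populations are steps of 1 escalation and not independent.

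**Figure D3:**
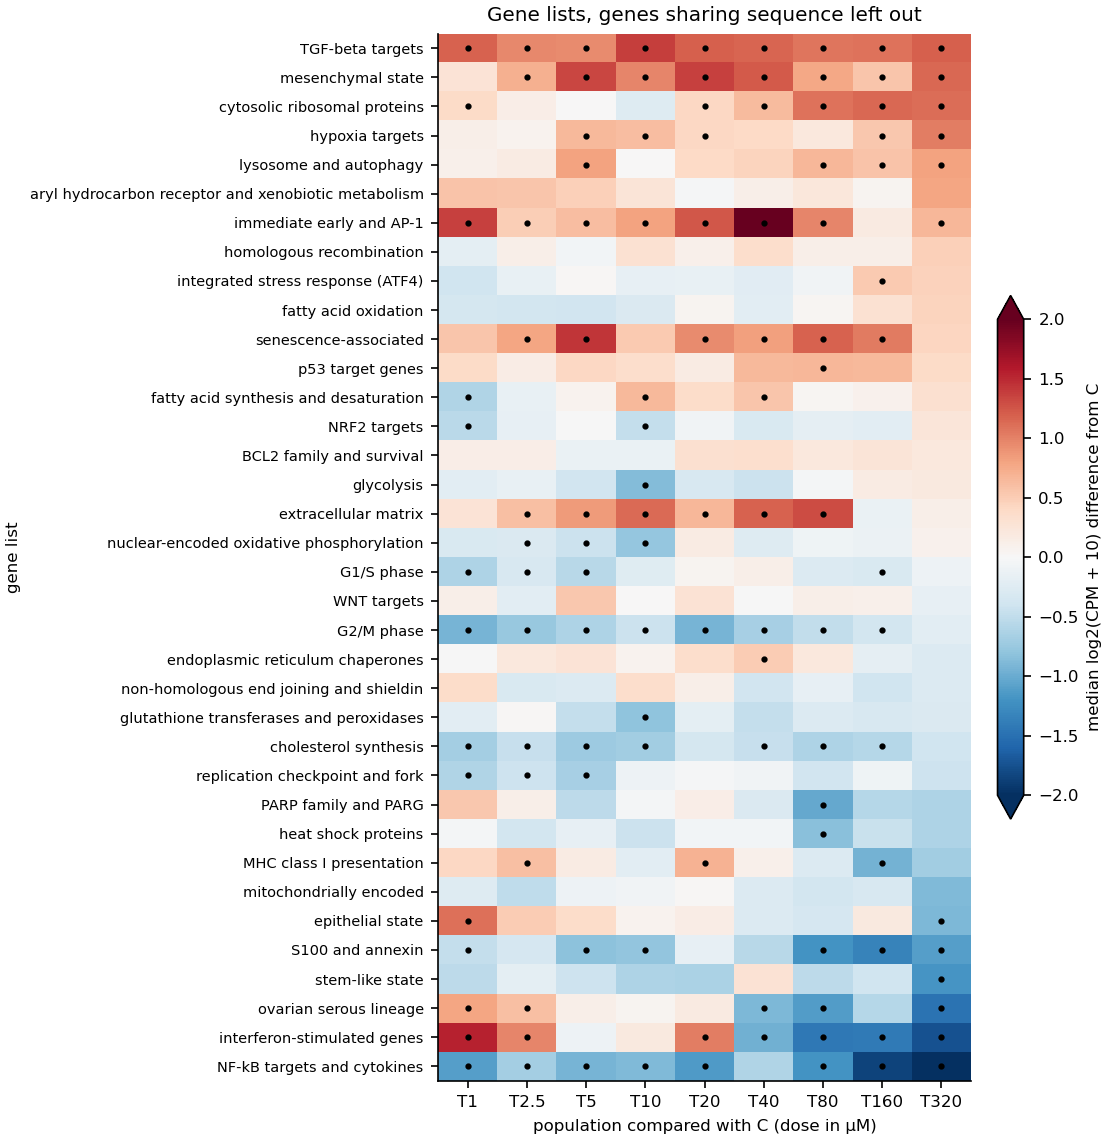
Median log2 difference from C of each gene list in each treated population, with genes that share sequence left out. Dots mark lists in the lowest or highest 2.5% of matched random lists.

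Other lists showed where T320 lay highest against C. TGF-beta targets had a median of 1.74 (1.19 with sharing genes left out), with 7 of 7 measured members higher: besides TGFBI, these included CTGF, a matricellular growth factor (587 to 2457 CPM), and ID2, a transcriptional inhibitor (8.45 to 75). Genes of the mesenchymal state had a median of 1.17 (1.14 with sharing genes left out), with 10 higher and 3 lower of 20. VIM, the intermediate filament of mesenchymal cells, was 3.39-fold higher (3.27 to 3.51; 636 and 2155 CPM), and AXL, a receptor tyrosine kinase, stood at 37.7 and 201 CPM. S100A4, a calcium-binding protein of motile cells, was among the lower members and fell from 4005 to 243 CPM (adjusted p = 0.00139), and it lies on chromosome 1. Hypoxia targets had a median of 1.18 (1.02 with sharing genes left out), with 9 of 12 higher and none lower, among them BNIP3L (25.3 to 121 CPM), KDM3A (21.9 to 95.9) and MXI1 (32.0 to 107). Immediate early and AP-1 genes peaked in T40 (median 2.63), where FOSB reached 800 CPM from 36.7 in C, and had a median of 0.75 in T320 (0.67 with sharing genes left out). Lysosomal genes had a median of 0.75 (0.80 with sharing genes left out), and HEXA (21.8 to 83.5 CPM, adjusted p = 0.00266), a subunit of hexosaminidase, rose. Senescence-associated genes had 1.25 (0.43 and percentile 91.3 with sharing genes left out): the CDK inhibitor CDKN1A (34.7 to 240, adjusted p = 0.00662), the stress cytokine GDF15 (6.31 to 119, 0.0050) and the galactosidase GLB1 (10.2 to 84.6, 0.00431) rose, while the CDK inhibitor CDKN2A stood at 1201 in C and 243 in T320. Ribosomal protein genes had 0.53, with 20 higher and 11 lower of 61, and 1.12 over the 13 that share at most 10%. No tested gene of the TGF-beta, mesenchymal, AP-1 or senescence-associated list shares over 10%. Their second medians therefore differ through the rescaling and the members that then reach 50 CPM, and not through members that share sequence.

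These 7 lists lay in the highest 2.5% of the matched lists. With a minimum of 200 CPM, ribosomal protein genes alone of the 7 stayed there (percentile 99.6). Some lists had fewer than 3 measured members at that minimum and were not placed, so absence there need not mean a lost difference. Genes with a trend, rising and falling, numbered 2 and 1 of 18 tested TGF-beta targets (2 and 1 adjusted over the list alone), 1 and 2 of 25 mesenchymal (1 and 1), 7 and 1 of 19 hypoxia (8 and 1), and 1 and 1 of 21 AP-1 genes (1 and 0). They numbered 3 and 2 of 20 lysosomal (3 and 2), 3 and 2 of 14 senescence-associated (3 and 2) and 13 and 0 of 61 ribosomal protein genes (13 and 0). With sharing genes left out they numbered 6 and 1 of 18 hypoxia targets, 2 and 2 of 15 lysosomal and 6 and 0 of 13 ribosomal protein genes, and the other counts were the same. Over C to T80, list counts leave sharing genes out. Rising and falling genes there numbered 1 and 0 of the TGF-beta, 2 and 1 of the mesenchymal and 1 and 0 of the hypoxia list. For AP-1 genes they were 4 and 0, for lysosomal 3 and 0, for senescence-associated 1 and 1 and for ribosomal protein genes 3 and 0. The hypoxia list's median was 0.70 in T5, 0.80 in T10, 0.72 in T40 and 0.29 in T80. The adjusted values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over 10 populations that are not independent.

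Lists lowest in T320 included epithelial and lineage genes. Epithelial genes had a median of -2.16, with 5 of 6 measured members lower and none higher (-0.90, percentile 2.1, with sharing genes left out). DSP, which anchors keratins at desmosomes, fell from 273 to 54.5 CPM (adjusted p = 0.00124), and KRT8, a keratin of simple epithelia, from 1027 to 219 (0.00557; 39.2% shared). CD24 went from 77.7 to 5.31 CPM (0.00785) and the protease inhibitor SPINT2 from 186 to 6.72 (0.0133), each with just over 10% shared. The ovarian serous lineage list had -1.33 (percentile 0.15; -1.48 with sharing genes left out), with SOX17, a transcription factor of Müllerian epithelium, at 390 CPM in C, 5.45 in T80 and 37.5 in T320, and EMX2, a patterning factor of the reproductive tract, at 69.5, 6.11 and 21.6. NF-kB targets had -1.39 (percentile 0.05; -2.31 with sharing genes left out): the cytokine IL32 fell from 94.7 CPM to 0 (0.00981) and the chemokine CCL2 from 115 to 7.08 (0.00619). S100 and annexin genes had -0.99 (percentile 0.41; -1.10 with sharing genes left out), with S100A16 down from 657 to 60.5 CPM (0.00142) and ANXA3 at 60.8 and 6.02, and the S100 genes named here lie on chromosome 1. Cholesterol synthesis had -0.58 (percentile 0.56; -0.39 and 3.8 with sharing genes left out). HMGCS1, an early enzyme of the pathway, stood at 129 and 44.9 CPM. Heat shock genes had -1.05 (-0.62, percentile 7.5, with sharing genes left out), with CRYAB at 66.4 CPM in C and 0 in T320 and HSPB1 at 1626 and 322 (26.1% shared). The stem-like list had -1.04 (percentile 0.95; -1.18 with sharing genes left out), although CD44 belongs to it, with ALDH1A2, a retinal dehydrogenase, at 115 and 5.66 CPM. Over genes listed in all 10 populations its median was 0.35. All metallothionein genes measured share sequence, so their -1.10 (percentile 1.80) is not interpreted.

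These, the interferon list and the G2/M list made up the 10 lists in the lowest 2.5%. With a minimum of 200 CPM 3 stayed there: epithelial (percentile 0.975), heat shock (0.55) and S100 and annexin genes (0.82). Lists with fewer than 3 measured members at that minimum were not placed. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 of 14 epithelial genes fell (8 adjusted over the list alone), 6 of 14 ovarian serous genes (9), 5 of 16 NF-kB targets (6), 5 of 12 S100 and annexin genes (5), 7 of 22 cholesterol genes (8) and 4 of 15 heat shock genes (5). None rose in these 6 lists. With sharing genes left out, 2 of 8 epithelial, 4 of 10 S100 and annexin, 7 of 20 cholesterol, 3 of 8 heat shock, 6 of 14 ovarian serous and 5 of 14 NF-kB genes fell. Of 11 stem-like genes 2 rose and 2 fell (3 and 4; 2 and 1 of 9 with sharing genes left out), and no metallothionein of 7 did either. Over C to T80, 5 ovarian serous, 3 S100 and annexin, 2 cholesterol, 2 NF-kB, 1 epithelial and 0 heat shock genes fell and 1 S100 or annexin gene rose, and the epithelial median in T80 stood at percentile 21.9 with sharing genes left out. The 10 populations are not independent, and the order within 1 escalation cannot separate dose from time in culture.

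DNA repair and drug target genes were examined because loss of PARP1, restored homologous recombination and drug efflux are known routes to PARP inhibitor resistance. PARP1, the main target of olaparib, fell from 399 CPM in C through 188 in T80 to 205 in T320 (1.95-fold lower, 1.79 to 2.13; -0.18 per step, adjusted p = 0.00635, and 0.0214 over C to T80). PARP1 differed by -0.93 in T320 when scaled by library totals, and it lies on chromosome 1 (226360691 to 226408079). TMM scaling, with factors of 0.922 in C and 1.12 in T320, makes this fall larger. It makes rises from C to T320 smaller, such as those of BRCA2, BRCA1 and TP53BP1 given below. Relative to all genes, the 42 genes from 225486835 to the end of the chromosome, which include it, had a median of -0.41, and the 50 genes before them (204073115 to 225428925) had 0.04. BRCA2 stood at 13.4 and 31.8 CPM (2.38-fold, 1.79 to 3.15; adjusted p = 0.384), with 12.7% of its end shared, and BRCA1 at 39.3 and 72.9 (0.231). Reads at the 3' end do not show whether the BRCA2 mutation was present or reverted. PARG, whose loss restores PAR chains, stood at 8.56 and 9.20 CPM (0.892), and TP53BP1, which blocks end resection, at 51.7 and 65.5 (0.630). CCNE1 stood at 47.6 and 33.6 (0.183) and MYC at 21.2 and 85.3 (0.342). SLFN11, which sensitizes cells to PARP inhibitors, was listed at 0 except at 5.74 CPM in T40 and 4.25 in T80. The efflux pump gene ABCB1 had no row in the matrix, so nothing is said about its level. VIM rose (adjusted p = 0.0161). PAX8, a marker of Müllerian epithelium, stood at 299 CPM in C, 544 in T1 and 160 in T320 and fell along the escalation (0.0146; 0.0497 without T320). EPCAM, an adhesion molecule of epithelia, was listed at 0 except for 4.98 CPM in T10, 5.17 in T20 and 3.8 in T160. Along the order of 1 escalation, edgeR's quasi-likelihood test (Benjamini-Hochberg) takes 10 populations that are not independent.

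As groups, repair genes lay inside the range of matched lists in T320. The homologous recombination list had a median of 0.58 in T320 (percentile 83.7; 0.48 and 83.5 with sharing genes left out) over 5 measured members, none of them 2-fold different. In the trend test 3 of its 22 genes rose and none fell (3 and 0 adjusted over the list alone). End joining and shieldin genes had -0.10 (percentile 38.1; -0.27 and 30.6), and 3 of 10 fell (3), among them XRCC5, the Ku80 subunit (334 to 165 CPM, adjusted p = 0.0123). The PARP family had -0.28 (percentile 17.5; -0.61 and 4.49), and 4 of 16 fell (5), among them PARP14, an interferon-induced mono-ADP-ribosylase (82.5 to 16.3 CPM, 0.00775). In T40 and T160 the PARP family lay in the lowest 2.5%, with medians of -1.02 and -1.16 over 3 measured members (percentiles 26.1 and 5.26 with sharing genes left out). With sharing genes left out, it lay there in T80 (1.16), and replication checkpoint genes did in T1 (0.70), T2.5 (1.78) and T5 (0.14). Replication checkpoint genes had -0.20 (percentile 13; -0.42 and 7.07), with HLTF, a fork remodeler, at 63.1 and 239 CPM. Of 17 tested 1 rose (0 adjusted over the list alone). ABC drug transporters had 1 measured member, and 1 of 10 tested rose (1). Over C to T80 no homologous recombination or replication checkpoint gene had a trend, 1 end joining and 1 PARP family gene fell, and 1 ABC transporter fell. The adjusted values come from edgeR's quasi-likelihood test (Benjamini-Hochberg) and 10 populations that are not independent.

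Metabolic and stress lists had mixed members in T320, and their values there with sharing genes left out follow a slash. Earlier populations are described for only part of these lists, so a place inside the range in T320 does not speak for them. In the integrated stress response list (median 0.56 / 0.46, percentile 94.1 / 94.7), the asparagine synthetase gene ASNS stood at 28.0 and 258 CPM, but 72.0% of its end is shared, and 3 of 24 genes rose and 1 fell (4 and 1 over the list alone). Among NRF2 targets (0.34 / 0.24, percentile 90.0 / 81.6), HMOX1, which degrades haem, rose from 14.6 to 222 CPM (adjusted p = 0.00124). In glycolysis (-0.30 / 0.19, percentile 8.86 / 66.8, so the direction turned), PFKP (39.0 to 213 CPM, 0.00172) and the neuronal enolase ENO2 (7.71 to 67.2, 0.00393) rose, while the enolase gene ENO1 of chromosome 1 stood at 4415 and 1526. In fatty acid oxidation (0.63 / 0.45, percentile 94.1 / 88.2), the nuclear receptor PPARA rose from 10.7 to 84.6 CPM (0.00987). Among matrix genes (median 0.25, but -0.06 with TMM and -0.02 with DESeq2 size factors; 0.11 with sharing genes left out; percentile 78.8 / 74.1), LAMB1 rose from 70.1 to 594 CPM (0.00176) and COL6A2 from 7.28 to 139 (0.00508), while SPP1 fell. In fatty acid synthesis (0.41 / 0.32, percentile 74.7 / 73.8) ELOVL5 rose from 25.6 to 92.0 (0.00671), and among p53 targets (0.38 / 0.38, percentile 73.6 / 80.8) XPC rose from 13.3 to 61.9 (0.00277). BCL2L11, a trigger of apoptosis, rose from 19.6 to 79.6 (0.00404) in the survival list (percentile 42.6 / 54.6), and DKK3 rose from 9.85 to 66.5 (0.00749) among WNT targets (-0.07 / -0.17, percentile 29.4 / 26.0). Xenobiotic metabolism (percentile 97.47 / 96.3, just under the limit), oxidative phosphorylation (94.8 / 81.1, with 23 of 44 genes left), mitochondrially encoded genes (6.80 / 15.9, with 3 of 13 left), chaperones of the endoplasmic reticulum (44.8 / 19.9) and glutathione enzymes (15.3 / 21.9) lay inside the range of the matched lists in T320. Earlier, oxidative phosphorylation genes were lower in T2.5 (percentile 0.23), T5 (0.05) and T10 (-0.58 / -0.78, below all matched lists), with 9 of 44 lower and 0 higher in T10, mitochondrially encoded genes in T1 (-0.67, percentile 0.095, but 26.9 with 3 genes left), T2.5, T20, T40 and T80, and glutathione enzymes in T10 (-0.68 / -0.80, percentile 0.30 / 0.21) and T40 (1.08 / 5.40). With sharing genes left out, the chaperones lay in the highest 2.5% in T40 (98.5). Basal keratins and nuclear-retained RNA had no measured member. Rising and falling genes numbered 2 and 2 of 15 glutathione enzymes (2 and 8 over the list alone). With sharing genes left out, 1 of 9 rose and 2 fell. In glycolysis such genes numbered 4 and 5 of 20, and among p53 targets 3 and 2 of 19. The survival list had 2 and 1 of 17, and WNT targets 2 and 1 of 10. Fatty acid oxidation had 5 and 1 of 21, and matrix genes 3 and 4 of 23. Trends are from edgeR's quasi-likelihood test (Benjamini-Hochberg), over 10 populations of 1 escalation that are not independent.

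Some genes were high only in between, and the 6 furthest above both ends were named by rule. COL3A1 reached 1950 CPM in T5 and was listed at 0 in T320. COL1A1, the main collagen of connective tissue, went from 5.24 CPM in C to 664 in T10 and 0 in T320, and IGFBP5 from 46.6 to 1082 in T5 and 53.1 in T320. RGS5, a G-protein regulator typical of pericytes, reached 519 CPM in T5 between 8.99 and 5.66, and VCAM1, a leukocyte adhesion molecule, was listed in T10 to T80 alone, with 142 CPM in T40. PTGDS, a prostaglandin synthase, reached 538 in T80 (15.8 in C, 11.7 in T320), but 40.7% of its end is shared and the drop falls on T160. Low in between were AURKB, the mitotic kinase (219 CPM in C, 49.5 in T1, 237 in T320), PHLDA2 (56.7, 9.62 in T5, 53.4), RGS10 (159, 42.5 in T5, 153) and CLDN11, a tight-junction protein (107, 18.4 in T1, 96.6). These are single libraries, and no test was made.

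The next question was at which steps expression moved most. From T5 to T10, 4 genes were listed for the first time and were furthest higher: TGFBI (0 and 190 CPM), VCAM1 (0 and 113), PRKCB (0 and 56.2) and CRISPLD1, a secreted protein (0 and 56.7). The small heat shock protein gene CRYAB (176 and 17.1 CPM), CCDC3 (117 and 14), the myosin light chain gene MYL9 (696 and 146) and the peroxidase gene GPX3 (499 and 108) were lower. From T80 to T160, LRRN2 (14.1 and 238 CPM), CDKN2A (89.2 and 555), L1CAM, an adhesion molecule of neural and invasive tumour cells (17.1 and 139), and CLDN11 (27.5 and 195) were higher, and the 4 genes furthest lower share sequence. Distances from C were 0.683 in T1, 0.592 in T2.5, 0.724 in T5, 0.843 in T10, 0.722 in T20, 0.839 in T40, 0.907 in T80, 1.02 in T160 and 1.05 in T320. Random parts of 1 population differed by at most 0.215. With sharing genes left out T80, T160 and T320 lay at 0.921, 0.927 and 1.01. Steps were longest from T80 to T160 (0.764), C to T1 (0.683) and T5 to T10 (0.597). With sharing genes left out, T80 to T160 (0.576) came after C to T1 (0.697), T5 to T10 (0.605) and T20 to T40 (0.603), so its first place rests on those genes. Steps were shortest from T1 to T2.5 and from T40 to T80 (0.398 each).

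The deposited metadata assign a state to each listed cell. How states were assigned is not given in the sources used here, so where a population holds a single state, that share is not read as composition. All 453 listed C cells were in state C and all 1223 of T1 in S1. S1 gave way to S2, which held 17.6% of T2.5 and 54.0% of T5 (49 to 59). T10 mixed S2 (66.8%), S3 (14.2%) and S4 (19.0%), and T20 held 65.2%, 23.3% and 11.6%. S4 held 75.9% of T40 and 92.1% of T80. All 1348 cells of T160 and all 560 of T320 were in S5, the 2 libraries in which genes that share sequence lost counts. Intervals are binomial and cover counting error only.

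**Figure D4:**
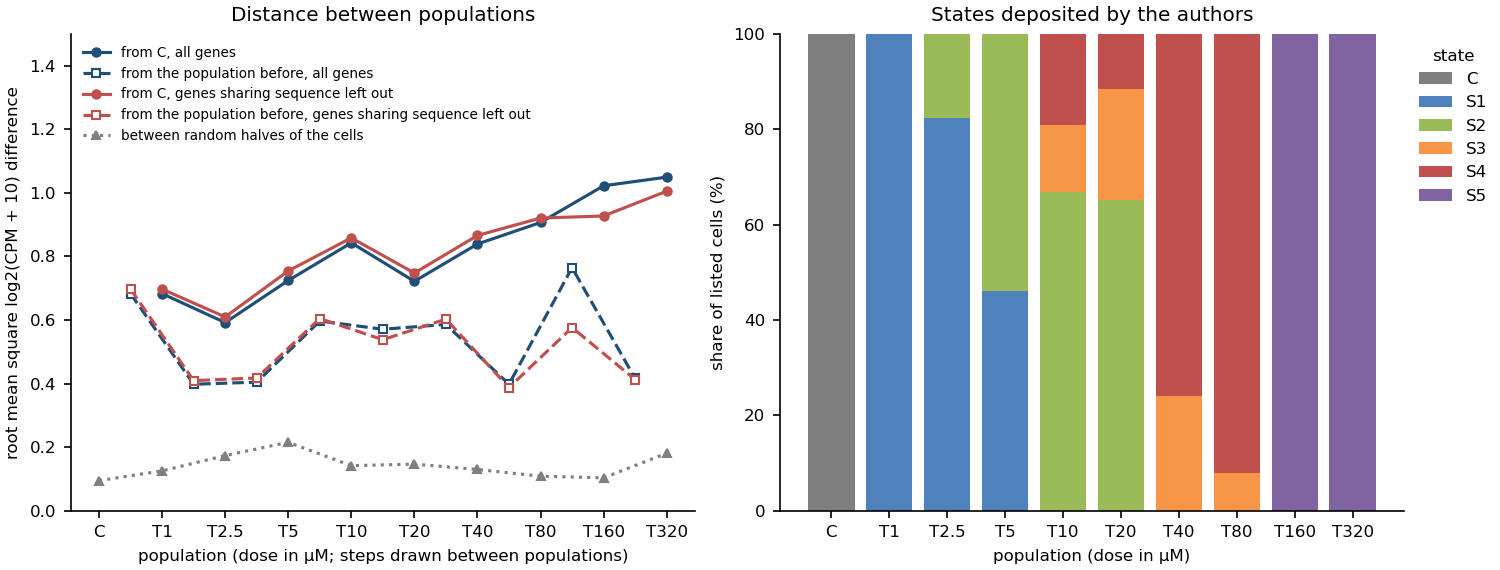
Left, distance of each population from C and from the population before it, with all genes and with genes that share sequence left out, beside random parts of 1 population. Right, percent of listed cells in each deposited state.

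Whether cells kept cycling was asked from transcripts of the cell cycle. Mitotic genes were lower at first exposure: PLK1, a kinase needed for mitosis, stood at 193 CPM in C and 57.9 in T1, ANLN, which builds the cleavage furrow, at 233 and 65.7, and CDCA8 at 148 and 37.8. Summed G2/M transcripts were 6602 CPM in C, 3693 in T1 (0.559 of C, 0.550 to 0.568), 3054 in T20 (0.463) and 6037 in T320 (0.914, 0.899 to 0.930). Summed G1/S transcripts were 2733 CPM in C, 1757 in T1 (0.643 of C, 0.628 to 0.658), 3023 in T40 (1.11 of C) and 2645 in T320 (0.968, 0.943 to 0.993). Counted per thinned cell, T40 lay below C instead, with 42.6% (40.4 to 44.8) against 46.9% (44.3 to 49.5) of cells with at least 3 G1/S UMIs. RRM2, the ribonucleotide reductase subunit, stood at 149, 42.0 and 39.6 CPM in C, T1 and T320, with 49.9% of its end shared. The G2/M list's median was -0.88 in T1 and -0.25 in T320 (percentile 1.62; -0.21 and 6.52 with sharing genes left out), and 0.01 there with a 200 CPM minimum, so the sum came closer to C than most members did. HMGB2, a chromatin protein, rose from 102 to 384 CPM (edgeR adjusted p = 0.00839). Of 47 G2/M genes 1 rose and 1 fell (1 and 1 over the list alone), and of 38 G1/S genes (median -0.01, percentile 26.9; -0.10 and 22.6 with sharing genes left out) 1 and 2 (1 and 2). Over C to T80, with sharing genes left out, 1 G2/M gene rose and 5 fell, and 0 G1/S genes rose and 1 fell. After thinning to 1000 UMIs, 77.9% of C cells, 42.6% of T1 cells and 60.04% of T320 cells had at least 3 G2/M UMIs.

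The metadata table listed 24.6% of C cells (22.6 to 26.6), 52.9% of T1, 48.7% of T2.5, 54.8% of T5, 51.9% of T10, 43.8% of T20, 44.2% of T40, 40.2% of T80, 51% of T160 and 42.0% of T320. G2/M transcripts were lower in listed cells (2390 CPM against 8496 in unlisted cells of C, 1325 against 9550 in T320), which is what a selection of G1 cells would give. How the cells were chosen is not given in the sources used here, so the percentages are not taken as the share of cells in G1. The listed cells were also deeper than the unlisted ones in each population, with a median of 5946 UMIs against 1670 in C, 2624 against 1341 in T1 and 1934 against 1794 in T320.

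Markers of other cell types were examined as a sign of mixture. Fibroblast markers, 6 of 10 analysed, summed to 157 CPM in C, 2430 in T5 and 297 in T320, led in T5 by COL3A1 (1950 CPM), which also belongs to the matrix list. In T320 FBLN1 and THY1 made up the sum (153 and 144 CPM). Endothelial markers, 5 of 9, went from 158 to 73.2 CPM, with TIE1, a receptor kinase on chromosome 1, falling from 121 to 6.37 CPM (edgeR's quasi-likelihood test over 10 populations that are not independent, Benjamini-Hochberg adjusted p = 0.0127). Immune markers, 3 of 15, summed to 0 in C and at most 43.9 CPM in T320. There the whole sum was CD68, which is also lysosomal and shares 75.4% of its end, while CD74 was at most 26.6 CPM, in T80, and listed at 0 in T320. Tissue markers of other epithelia, 3 of 12, summed to at most 15.7 CPM. The 5 red cell markers had no row in the matrix and were not analysed.

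The last analysis, chosen after the data were examined, asked whether neighbouring genes shifted together. Genes of chromosome 1 did: the median of its 642 genes that share little sequence, relative to all genes, was -0.01 in T1, -0.22 in T5, -0.46 in T10, -0.51 in T20, -0.73 in T40, -0.68 in T80, -0.49 in T160 and -0.53 in T320. A stretch of its long arm (204073115 to 225428925) was an exception, at -0.51 in T80 but 0.10 in T160 and 0.04 in T320. PARP1, NMNAT2, S100A4, S100A16, IFI6 and FLG lie on chromosome 1 outside that stretch. A stretch of chromosome 19 (48615328 to 55087923) lay 1.12 above all genes in T80, 0.44 in T160 and 0.96 in T320. It holds PPP1R15A, a stress-induced phosphatase subunit (28.0 CPM in C, 87.0 in T80 and 159 in T320), and the electron transfer flavoprotein gene ETFB (37.5, 152 and 140; 28.8% shared), but also KLK5, which fell. Other stretches shifted too. Relative to all genes, 3 neighbouring windows of chromosome 3 (3144628 to 62297613) stood at 0.65, 0.68 and 0.69 in T320, the first window of chromosome 9 (470291 to 35073249) at -0.49 in T5 and -0.53 in T320, and a window of chromosome 20 (25407727 to 37317260) at 0.69 in T320. The shift of chromosome 1 also divided states inside single libraries. Relative to all genes, chromosome 1 lay at -0.24 in S4 against S2 and -0.31 in S3 against S2 of T10, and at -0.24 in S2 against S1 of T5. Other chromosomes differed between S4 and S2 of T10 as well, chromosome 2 by -0.27 and chromosome 14 by 0.33. DNA was not measured in these libraries.

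**Figure D5:**
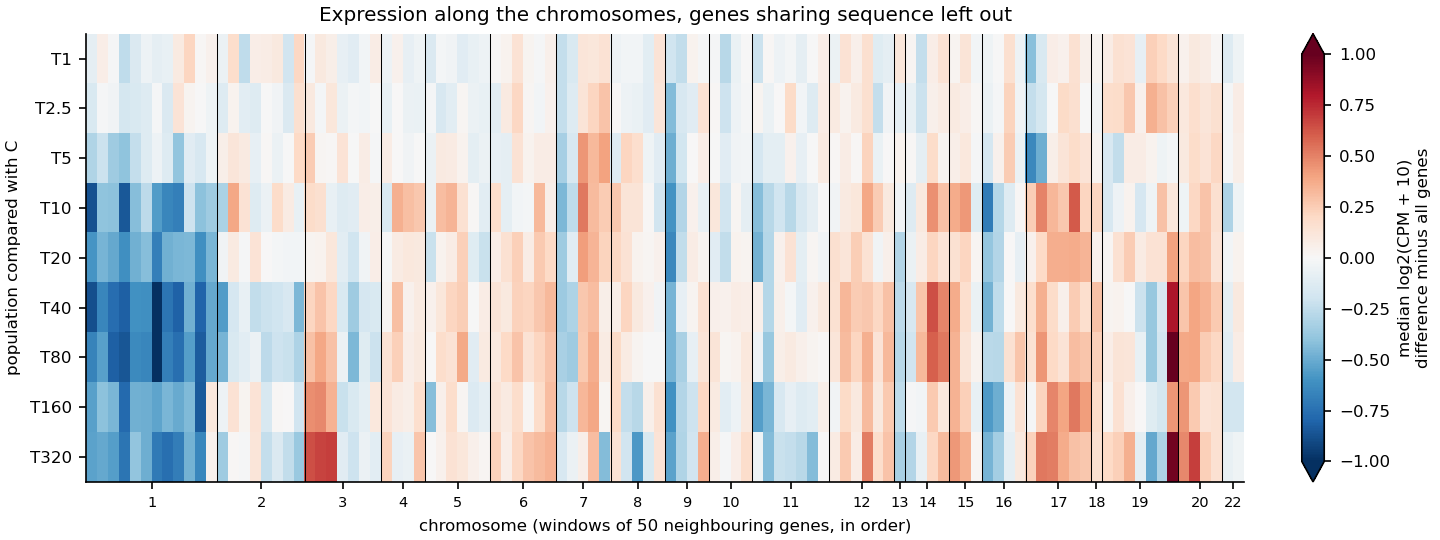
Median log2 difference from C in windows of 50 neighbouring genes along the chromosomes, for the 9 treated populations, with genes that share sequence left out.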

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

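Settings that concern shared sequence, values listed at 0, the endpoint T80 and the trend over C to T80 were chosen after the data were examined, and the others before. The count of genes higher from C to T320 (712) was 416 with TMM, 450 with DESeq2 size factors, 1262 with no CPM minimum, 162 with 200 CPM and 389 at T80, and the count lower (537) was 846 with TMM, 914 with no minimum and 214 with 200 CPM. From C to T1, 317 higher became 502 with no minimum and 88 with 200 CPM, and 202 lower became 61 with 200 CPM, as a lower or higher minimum admits more or fewer genes. Genes with a falling trend (1024) numbered 1694 by DESeq2, 517 over C to T80 and 455 there with sharing genes left out. Rising ones (914) numbered 1501 by DESeq2, 311 with dose as the covariate, 410 over C to T80 and 365 there with sharing genes left out. Leaving out 1 population gave 488 to 981 rising and 537 to 1061 falling, lowest without T320. Lists in the highest 2.5% (7) came to 1 with 200 CPM, and lists in the lowest 2.5% (10) to 3, or to 6 with sharing genes left out. At 200 CPM some lists had fewer than 3 measured members and were not placed. The G2/M list's median of -0.25 became 0.0076 with 200 CPM, and the stem-like list's -1.04 became 0.35 over genes listed in all 10 populations. By limma-voom the slope of SPOCK1 (1.05) was -0.067 and that of PCDHB10 (0.98) was -0.26. The distance from T80 to T160 (0.764) was 0.962 with a pseudocount of 1, 0.594 with no minimum, 1.11 with 200 CPM and 0.576 with sharing genes left out. With a pseudocount of 1 the distances from C were 1.02 in T10, 1.04 in T40, 1.13 in T80, 1.32 in T160 and 1.37 in T320. With no minimum they were 0.539 in T1, 0.688 in T10, 0.674 in T40, 0.713 in T80, 0.819 in T160 and 0.853 in T320, and with 200 CPM 1.03 in T80, 1.28 in T160 and 1.26 in T320. G1/S transcripts in T1 (0.643 of C) were 0.627 as a mean over cells, 0.484 as the share of thinned cells and 0.598 with sharing genes left out, and in T320 (0.968) 0.907 and 0.898 by the latter 2. G2/M transcripts in T1 (0.559) were 0.569 as a mean over cells and 0.547 as thinned cells, and in T320 (0.914) 0.881, 0.771 and, with sharing genes left out, 0.883. Among cells with at least 1145 UMIs, the table listed 28.9% of C, 63.7% of T1, 56.9% of T2.5, 64.0% of T5, 54.5% of T10, 56.2% of T20, 47.7% of T40 and 58.0% of T160. The cause was not tested for any of these shifts except where stated.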

Other observations

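All tests below except the comparison with random walks were chosen only after the result was seen.

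Genes listed at 0 in C and well above it in T320 were first listed at different steps. A first listing is not a measured onset of expression, since a value listed at 0 is not a measured absence. Of 15 genes listed at 0 in C and at 50 CPM or more in T320, 10 were first listed by T5, 4 at T10 or T20 and 1 at T40 or T80. Clustered protocadherins are adhesion molecules of neurons. Of 15 genes of the B group on chromosome 5, 14 were listed at 0 in C, and 13 of these were listed above 0 in T80 and 8 in T320. Of the 5 that share at most 10% of their ends, all were listed at 0 in C and above 0 in T80, and 2 in T320. How many of all genes at 0 in C were above 0 later was not counted, so these numbers have no reference. C held 9343704 UMIs and listed 1138 genes at 0, T80 7524689 and 1107, and T320 2826113 and 1901. The lower numbers in T320 may therefore reflect its lower depth. The window of 50 genes around the clustered protocadherins, which covers other genes, had a median of -0.12 in T80, and no test was made. PCDHB10, which shares no sequence by the measure used here, and PCDHB16 were listed at 0 from C to T2.5 and at 71.0 and 79.6 CPM in T80. PCDHB11 stood at 0 in C and 40.1 CPM in T80, and PCDHB2 at 2.25 and 39.7. The last 3 share 14.7% to 35.1% of their ends with other genes, so reads of 1 member can count for another. In the other direction, 27 genes that share little sequence were at 50 CPM or more in C and listed at 0 in T320.

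Genes that resemble other genes lost counts at T160 and T320. The median difference from T80 to T160 of genes sharing over 80% of their ends lay at -1.80 relative to genes sharing none, so reads shared between genes may have been left out in these 2 libraries and counted in the others. A fall in ribosomal protein expression is argued against by the median of 0.22 of ribosomal protein genes that share at most 10%. Any other difference in the preparation or processing of T160 and T320, which also hold all cells of state S5, stays open, and so does the part of S5 that rests on it.

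Genes of chromosome 1 lay lower together from T10 on and in the later states, except for a stretch of the long arm (204073115 to 225428925) that stood at 0.10 in T160 and 0.04 in T320 after -0.51 in T80. The spread of the windows' medians in T320 (SD 0.349) was above the highest of the shuffles (0.176), which argues against chance placement of single genes. That spread covers the windows of the other chromosomes too, so it does not test chromosome 1 by itself. Shuffling also breaks any ordinary likeness of neighbouring genes. Inside the T10 library S4 lay at -0.24 against S2, where random parts gave 0.006, but states assigned from expression would differ more than random parts do, and chromosomes 2 and 14 stood at -0.27 and 0.33 in that contrast, so a difference between libraries is left open for the shifts between populations. A lower dosage of the whole chromosome was left undecided: the lowest percent of its genes below the median of all genes was 72.7 over T10 to T320 (highest 87.2), between bounds of 60 and 75 that were set after the medians were seen, first for T80 alone and then for T10 to T320, and that stretch runs against a shift of the whole chromosome in T160 and T320. A candidate explanation is outgrowth of cells with fewer copies of most of it, but no DNA was measured, a takeover by another clone or line remains open, and whether this accounts for the fall of PARP1 was not tested.

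The 1938 genes with a trend need not mean a steady drift with dose. None of 99 random orders of the populations gave more than 1 gene, and the real order was the only 1 of 100 with as many. Random orders break the descent of each population from the one before. They therefore argue only against an order without any structure, and cannot exclude chance changes along 1 lineage. Random walks, in which each population inherits the one before and each step has a random sign, gave 4486 to 4715 genes in 20 of 20 walks. Changes without a common direction, passed on from one population to the next, may therefore be enough for a count of this size, although sampling noise and library effects accumulate in such walks. By construction the squared distance of a walk equals on average the sum of its squared steps, and from C to T320 it was 43.2% of that sum after the sampling part was taken from both (40.9% before), so the walks are wider than the data.

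Before the scan along the chromosomes, 3 tests were run on the 15 genes listed at 0 in C and at 50 CPM or more in T320, and they were set aside for it. These genes had a UMI in a median of 13% of T320 cells, which the minimum of 50 CPM largely fixes, so this value decides nothing. Of 1091 T320 cells thinned to 1000 UMIs, 35.7% had none of these genes, against 28.8% if all cells were equal, which lay between the bounds of 20 and 50 and left a minority of expressing cells undecided. Of the 14 with a position, 0% had another of them within 1 Mb, as in the median of 1000 random draws.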
